A study of Arabidopsis thaliana with 12 samples.

How the data were processed

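Total RNA of 12 samples, 6 at 20 µE and 6 at 200 µE of blue light for 48 h, was measured on arrays of which only the processed value table was used here. Group and replicate number were taken from the sample titles. The deposited values are linear intensity in arbitrary units; the array's chemistry, background correction and scaling by the authors are not given in the sources used here. Read from the values themselves, the deposited intensity of each column averages between 0.814 and 1.04, 12.4 to 18.3% of a column's values are exactly 0, and up to 2 values per column stop just below 100. The intensities therefore look floored at 0 and capped, and levels close to either end are bounds. No 2 columns were identical. All 12 columns were mapped to samples.

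Probes were named through the platform annotation given for the table, joined by gene identifier to a gene table of the TAIR10.1 assembly. Of 3439 probes, 692 listed 1 gene, 870 several and 1877 were not listed; the latter are unnamed here, not without a gene. Of the 692 identifiers, 690 were found in the gene table, and 2 kept the annotation's name. No coordinates are given because no genome build is named for the array. The 2 probes of 1 gene were averaged. What is said of a gene's function is background knowledge.

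Each column's zeros were set to the 1st percentile of its positive values, so that positive values under that percentile lay below the zeros. The log2 values were quantile-normalised over all 3439 probes. This was done because medians and interquartile ranges of the columns spanned 1.75 and 1.63 on the log2 scale. The limit set for a table to count as normalised was 0.1. The 1561 listed features were tested with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, two-sided, as 200 µE minus 20 µE, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Features listed at 0 throughout numbered 116; they had no spread of their own after quantile normalisation but entered limma's shared estimate of it. The fits over 12 columns and over couple means were repeated without them. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, and again estimated) and, as a description, with fry; only the plastid ribosomal list qualified. No measured list member carried a reference name of another gene.

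Same-numbered columns of the groups deviated from their group means together (correlations 0.154 to 0.503 for the 6 pairs). Each of the 12 columns correlated best with its own number in the other group, so the numbers were taken to pair the columns. The labels do not say what a number marks. The main test, fixed beforehand, did not use this pairing, and fits with the replicate number or the couple as a block were set beside it. Within groups, columns 1 and 2, 3 and 4, and 5 and 6 also deviated together (0.157 to 0.755, against at most 0.104 between couples). The values themselves, at 200 µE, correlated at 0.937 to 0.970 within couples and at up to 0.953 between couples. The labels do not say whether samples came from separate plants, and p-values over 12 columns treat each as independent, measuring a spread that may be partly technical. A fit on the 3 couple means per group was therefore set beside it. Both were tested on simulated data with the measured spread within and between couples and 200 changed features of 1561, 187 of them with values above 0 in the table. Among these 187, the 12-column fit recovered 57.2% of changes of 1 and 84.1% of changes of 2 on the log2 scale, but 37.8% of all its calls were false. The fit on couple means recovered 16.1% and 52.2%, with 6.52% false. Without the features at 0 throughout it recovered 10.9% and 63.1%, with 5.73% false. With the couple as a block, the fit recovered 2.5% and 13.9% with those features and made 0 calls without them. The simulated couples shared nothing between the groups. A false share also depends on how many features are changed, so these shares are not estimates for the real calls.

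Genes were named by a rule: the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 value above the 25th percentile; in each list the 2 largest rises and 2 largest falls past the threshold, or else the smallest p; and 10 blue or high light genes, none of which was measured alone. SBPASE, CHLM and the genes of the closing observations were added after their values were seen. The test, the lists, the naming rule and most other settings were fixed before the data were examined. The other settings chosen then were the replicate block, other normalisations, a filter on dim genes, a pseudocount of 0.0583 in place of the floor, a variance trend, array weights, a threshold of 0.01 and leaving out each column; averaging of couples, leaving out couples, leaving out features at 0 throughout and other feature sets were added afterwards.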

Results

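Transcript levels were measured on arrays in total RNA of wild-type Arabidopsis thaliana plants of the Landsberg ecotype after 48 h in blue light. The labels name 2 intensities, 20 µE and 200 µE, µE being the usual shorthand for a photon flux, and 6 samples at each, numbered 1 to 6 in both groups. The comparison asked which transcripts differ between plants kept in bright and in dim blue light. The tissue, the age of the plants and the number of plants per sample are not given in the labels. The table held 3439 probes, each with an intensity in arbitrary units. For 692 probes the annotation named 1 gene, giving 691 genes, and for 870 it named several. The precision was limited by the number of arrays. Columns 1 and 2, 3 and 4, and 5 and 6 of a group shared deviations from the group mean more than other columns did. Each such couple was therefore also averaged and counted once. Means ± SD are over these 3 couple means per group. The words rose and fell are used only for genes that passed the test (limma, adjusted p under 0.05) both over the 12 columns and over the couple means. Neither test pairs columns of the same number. For the genes named by rule, calls lost when couples were compared pair by pair are given below. Among the tested features, 116 were listed at 0 in all 12 columns, and values given without them are from fits repeated after the data had been examined.

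The largest rises at 200 µE were in genes whose mean intensity at 20 µE was at most 0.531 units. The transcript of AT5G52810, known as SARD4 and encoding a reductase of pipecolic acid synthesis, rose from 0.277 ± 0.101 to 3.03 ± 0.902 units (SD, n = 3 couples), a change of 4.27 ± 0.28 (SE) on the quantile-normalised log2 scale with an adjusted p of 7.8e-08 over 12 columns and 0.0037 over couple means. AT3G07790 rose from 0.111 ± 0.020 to 1.11 ± 0.086 units (log2 change 5.33 ± 0.56), and AT1G73120 from 0.433 ± 0.201 to 5.72 ± 1.77 units (4.49 ± 0.47). AT1G16080 rose by 3.63 ± 0.48 on the log2 scale, to a mean of 4.56 units. AT5G36470 rose from 0.212 ± 0.055 to 0.778 ± 0.241 units, AT1G51080 from 0.139 ± 0.043 to 0.238 ± 0.064 units and AT4G38490 from 0.186 ± 0.048 to 0.434 ± 0.062 units. Their log2 changes were 3.47, 3.03 and 3.02 after quantile normalisation, but 1.86, 0.82 and 1.25 without normalisation and 2.58, 1.83 and 2.15 with a pseudocount in place of the floor. Of the 10 genes with the largest rise, 7 passed over couple means. The other 3 were AT-HF, AT3G18870 and AT3G57570. AT-HF, an enzyme of histidine synthesis, had a log2 change of 3.36 ± 0.89 (adjusted p = 0.060 over couple means and 0.034 with the couple as a block). AT3G18870, an mTERF protein of the family that acts on organelle transcripts, changed by 3.13 ± 0.77 (0.051 and 0.073), and AT3G57570 by 3.51 ± 1.02 (0.072 and 0.088). Without normalisation the changes of AT-HF, AT3G18870, AT3G57570 and AT3G07790 were 1.82, 0.90, 1.74 and 3.34. All 10 were higher at 200 µE under each of the 3 scalings tried, and after quantile normalisation every 200 µE column exceeded every 20 µE column for all 10. In deposited units the columns of AT-HF overlapped. Without the features at 0 in all columns, AT-HF, AT3G18870 and AT3G57570 passed over couple means as well (adjusted p = 0.022, 0.018 and 0.028).

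The largest falls led to values close to the lower end of the scale, so that their size rests in part on the floor set for values listed at 0. DRT101, named after a screen for DNA damage repair and toleration, fell: it measured 1.25 ± 0.601 units at 20 µE and was listed at 0 in all 6 columns at 200 µE, so that no fold is given (adjusted p = 1.1e-07 over 12 columns and 0.0046 over couple means). AT1G79220, another mTERF protein, fell from 1.03 ± 0.466 to 0.016 ± 0.016 units (log2 change -4.86 ± 0.90), with 2 of its 6 columns at 200 µE listed at 0. Its column 3 at 200 µE, at 0.0024 units, was placed lower (-7.67 on the log2 scale) than these zeros (-6.24). AT2G32040, a folate transporter of the chloroplast envelope, fell from 1.80 ± 0.938 to 0.060 ± 0.027 units (-3.79 ± 0.61). AGL54, a MADS-box transcription factor, fell from 1.22 ± 0.070 to 0.044 ± 0.021 units (-3.62 ± 0.40, adjusted p = 4.2e-05 over 12 columns and 0.0092 over couple means). AT1G13970, AT1G35210, AT2G33180, AT4G39570 and AT4G16060 fell too, with log2 changes of -3.35, -3.31, -2.99, -2.95 and -2.92. AT4G18540 changed by -3.05 ± 0.78 and missed the threshold over couple means (adjusted p = 0.056). It passed without the features at 0 in all columns (0.021). Its column 2 at 200 µE lay at -7.52 on the log2 scale, against -3.77 to -2.92 in the others, and the change was smaller without that column. Of the 10 genes with the largest fall, 9 passed over couple means, and all 10 were lower at 200 µE under each scaling. After quantile normalisation the columns of the groups separated for all but AT4G39570, at -1.51 in column 5 at 200 µE and -1.59 in column 6 at 20 µE. The size of the falls depended on the setting: for the 9 genes other than DRT101 the log2 change lay between -3.16 (AT2G32040) and -1.60 (AT4G16060) with a pseudocount in place of the floor, and between -6.39 (AT1G79220) and -4.06 (AT2G33180) without normalisation. When the couple means were also compared pair by pair, with the couple as a block, AT5G36470, AT1G79220, AT2G32040, AT1G13970, AT4G39570 and AT4G16060 no longer passed, with adjusted p between 0.056 (AT1G13970) and 0.122 (AT4G16060). All 6 passed in that comparison without the features at 0 in all columns (0.0042 to 0.016). Without columns 1 and 2 of both groups, AT4G39570 and AT4G16060 gave adjusted p of 0.107 and 0.072, and without columns 3 and 4 AT4G39570 gave 0.063.

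**Figure D1:**
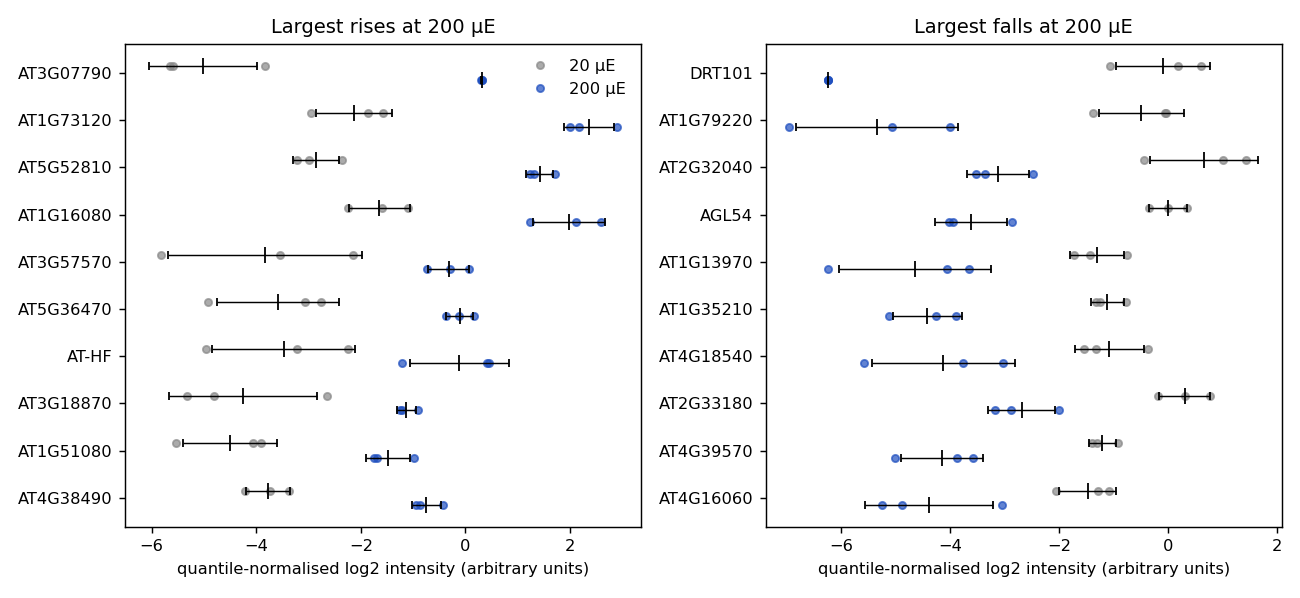
Quantile-normalised log2 intensity (arbitrary units, x axis) of the 10 genes with the largest rise and the 10 with the largest fall; each point is the mean of 2 neighbouring columns of 1 group, vertical ticks are group means and bars are SD (n = 3). The groups lie apart for every gene shown, by 3.02 to 5.33 among the rises, and DRT101 at 200 µE lies at the floor set for values listed at 0.

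Of the 303 members of 23 gene lists fixed before the data were examined, 16 had a probe naming that gene alone, and these belonged to 8 lists. Of the Calvin cycle list, 2 of 20 members were measured: PRK, the phosphoribulokinase that regenerates the acceptor of carbon dioxide, rose by 1.22 ± 0.27 on the log2 scale (0.600 ± 0.069 to 0.761 ± 0.192 units, adjusted p = 0.00052 over 12 columns and 0.042 over couple means). It kept that direction under each scaling, but passed neither without normalisation (log2 change 0.32, adjusted p = 0.15) nor over couple means with the couple as a block (adjusted p = 0.11, but 0.042 without the features at 0 in all columns). PRK was the only one of the 16 to pass in both tests over all features. The other measured member, SBPASE, was listed at 0 in all 20 µE columns and in 5 of the 200 µE columns, and did not pass.

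None of the 6 measured photosystem, antenna and chlorophyll synthesis genes passed over couple means (limma; 2 at an unadjusted p under 0.05). The light-harvesting gene LHCB1.5 had a log2 change of -0.59 ± 0.18 (9.26 ± 1.61 units at 20 µE, 7.04 ± 1.09 at 200 µE) and passed over 12 columns (adjusted p = 0.0069) and over couple means with the couple as a block (0.035), but not over couple means without the block (0.079), with it when the features at 0 in all columns were left out (0.157), or without normalisation (0.062). Of the 2 measured photosystem II core genes, PSBY had a log2 change of 0.67 ± 0.24 and PSBW of -0.48 ± 0.20, again past the threshold over 12 columns alone (adjusted p = 0.0066 and 0.024, against 0.12 and 0.16 over couple means). The call of PSBW was lost without column 1 or 2 at 20 µE or 5 or 6 at 200 µE (adjusted p between 0.0507 and 0.0539), or without columns 1 and 2, or 3 and 4, of both groups (0.096 and 0.093). Without columns 3 and 4 of both groups LHCB1.5 and PSBY gave adjusted p of 0.054 and 0.086. PSAN of photosystem I (log2 change -0.42 ± 0.37), the chlorophyll synthesis enzyme CHLM (-0.34 ± 0.33) and the geranylgeranyl reductase CHLP, AT1G74470 (-0.22 ± 0.17), did not pass. The change of CHLM depended on the scaling: it was -1.38 without normalisation (0.851 ± 0.387 to 0.305 ± 0.016 units) and passed there over 12 columns (adjusted p = 0.00028), but -0.02 under median centring (0.93). CHLP passed with the replicate number as a block (adjusted p = 0.023), with array weights (0.010), without replicate 4 at 20 µE (-0.30, adjusted p = 0.046) and without columns 3 and 4 of both groups (0.0245), and PSAN with array weights (-0.87, adjusted p = 0.00070). CHLP did not pass over couple means with the couple as a block (0.184, and 0.584 without the features at 0 in all columns). Under median centring LHCB1.5, PSBW, PSAN and CHLP changed sign, to 0.97, 1.60, 1.12 and 1.47. All 4 passed there over 12 columns as higher (limma, adjusted p = 0.00031, 2.6e-06, 0.0032 and 2.8e-05). Without normalisation PSBW and CHLP changed sign too (0.24 and 0.11), so that no direction is given for any of the 4 genes. PSBY was higher under each scaling, by 2.01 under median centring. LHCB1.5 belongs to a family of near-identical copies that its probe could share.

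Of the 6 measured plastid ribosomal proteins (39 in the list), 3 were higher and 1 lower over 12 columns and 2 did not pass, whereas without normalisation 1 was higher and 4 lower. When adjusted over the list alone 4 passed, and with the replicate number as a block 3 did. None passed over couple means (limma; 2 at an unadjusted p under 0.05). RPL29 (AT5G65220) had a log2 change of 0.87 ± 0.24 (2.45 under median centring) and RPS10 (AT3G13120) of 0.71 ± 0.26, the latter reversed, at -0.74, without normalisation. RPS10 passed there over 12 columns as lower (limma, adjusted p = 0.016). RPL34 (AT1G29070) was listed at 0 in all 200 µE columns and in 2 of those at 20 µE, where it measured 0.185 ± 0.164 units; its call was lost without columns 1 and 2, or 3 and 4, of both groups (adjusted p = 0.21 in either case). The list's median log2 change was 0.42 and its mean 0.066, and without normalisation the median was -0.83. As a set these genes were not shown to differ from the others (limma's camera, adjusted p = 0.16, and adjusted p = 0.32 with an estimated correlation). Limma's fry, which makes no comparison with the other genes, gave p of 0.012 over 12 columns and 0.065 over couple means. Of the single measured members of 2 further lists, the plastid peroxiredoxin PRXIIE (AT3G52960) had a log2 change of -0.95 ± 0.33 (adjusted p = 0.014 over 12 columns, 0.11 over couple means, 0.14 without columns 3 and 4 of both groups; log2 change -2.92 without normalisation, -1.56 under median centring and -0.60 with a pseudocount), and the fatty acid thioesterase FATB of 2.42 ± 0.68 (0.0013 and 0.068, the latter 0.029 without the features at 0 in all columns). FATB had deposited means of 0.147 ± 0.113 and 0.140 ± 0.028 units and did not pass without normalisation (log2 change 0.38, adjusted p = 0.55). No probe named alone a member of the lists for flavonoid synthesis, early light-induced proteins, photoreceptors, sigma factors, root, seed or senescence, so that other tissues or states were not assessed here.

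**Figure D2:**
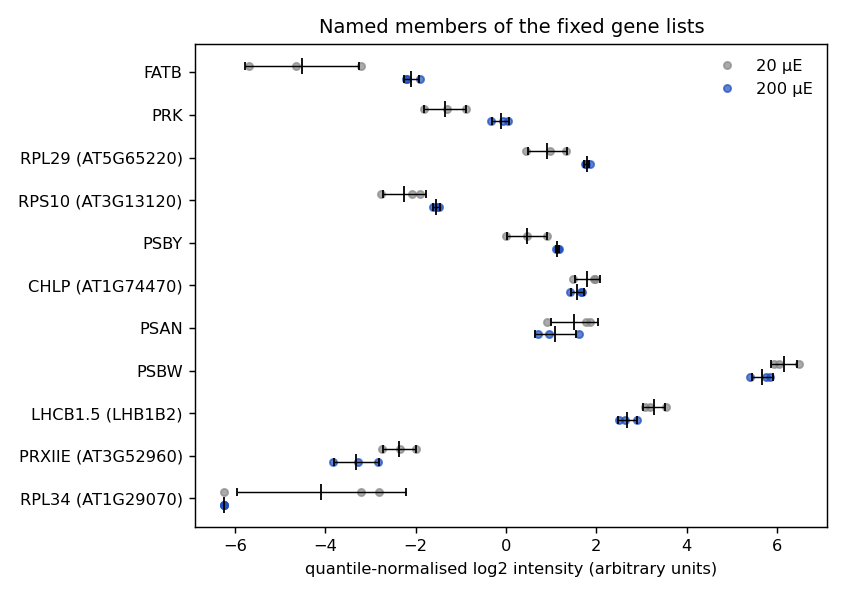
Quantile-normalised log2 intensity (arbitrary units, x axis) of the named members of the fixed lists; points are means of 2 neighbouring columns, vertical ticks group means and bars SD (n = 3 per group). PRK is the only gene shown that passed over 12 columns and over couple means with all features tested; LHCB1.5, PSBW, PSAN and CHLP change sign under median centring, and PSBW, CHLP and AT3G13120 without normalisation.

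Over the 1561 tested features (691 genes and 870 probes shared by several genes), 768 differed over 12 columns, 361 higher and 407 lower at 200 µE (limma, adjusted p under 0.05). Over couple means 329 differed, 159 higher and 170 lower, and 326 passed both tests. Comparing couple means pair by pair gave 243. Without the 116 features at 0 in all columns the counts were 786 over 12 columns, 380 over couple means and 485 pair by pair. On simulated data built with such couples and 200 changed features, 37.8% of the calls over 12 columns and 6.52% of those over couple means were false. Without the features at 0 in all columns the latter share was 5.73%. Such shares depend on how many features change, so they are not estimates for the calls made here. Among the 691 genes with a probe of their own, 333 passed over 12 columns (153 higher, 180 lower) and 135 over couple means (59 higher, 76 lower), all 135 in both. Of these, 118 had the same direction under all 3 scalings, 45 higher and 73 lower.

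The direction of many changes depended on the scaling, and the 2 groups had differently shaped distributions. Median intensity was 0.504 ± 0.079 units at 20 µE and 0.195 ± 0.020 at 200 µE (SD, n = 6 columns), while the brightest hundredth of probes held 26.2 ± 3.4% of the summed intensity at 20 µE and 39.2 ± 1.5% at 200 µE. Values listed at 0 made up 13.0 ± 0.86% and 17.3 ± 0.70% of the columns. Without normalisation the median change over features was -1.46 on the log2 scale and 1168 features passed, 9.68% of them higher at 200 µE, against 47.0% after quantile normalisation and 47.8% of 1068 after median centring. The counts of 1168 and 1068 include, as lower, all 116 features at 0 in all columns, whose values are the floor alone. Without them, 1049 features passed as deposited (10.8% higher) and 938 after median centring (53.6% higher), against 786 (46.3% higher) after quantile normalisation. These fits still held 42 features listed at 0 in all 20 µE columns but not in all 200 µE columns. The floor, lower at 200 µE, can make such features lower as deposited or under median centring.

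**Figure D3:**
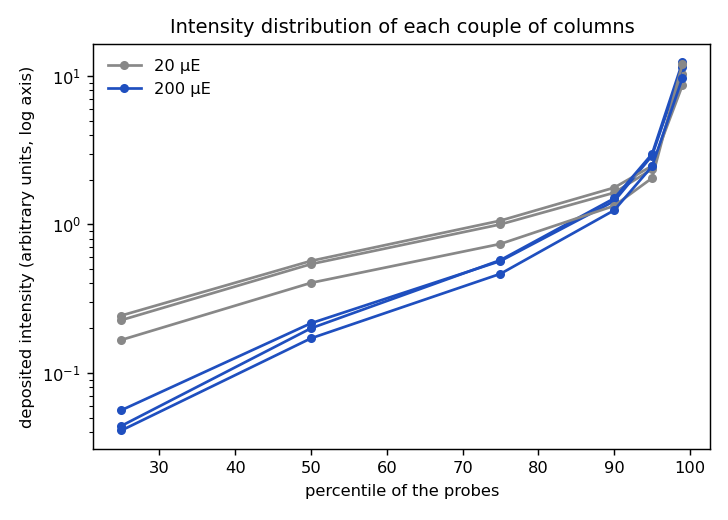
Deposited intensity (arbitrary units, log axis) at the 25th to 99th percentiles of the 3439 probes; each line is the mean of 2 neighbouring columns, 3 per group. The 200 µE lines lie below the 20 µE lines at the median (0.171 to 0.216 against 0.404 to 0.568 units) and within couples above them at the 95th percentile.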

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

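Apart from the comparison of the real grouping with other splits, the tests in this part were chosen after the results they bear on had been seen. In 6-column groups, 4 of 70 sets of values held a column apart from the rest, against 3.5 by chance (1 in 20). AT4G18540 measured -7.52 on the normalised log2 scale in column 2 at 200 µE, the other columns lying between -3.77 and -2.92. Its deposited value there was 0.0031 units, a positive value that the floor set for zeros left below listed zeros (-6.24). PSBY measured 1.05 in column 6 at 200 µE against 1.14 to 1.18, RPL29 (AT5G65220) 1.96 in column 6 against 1.72 to 1.80, and RPS10 (AT3G13120) -1.83 in column 1 against -1.55 to -1.42. Among the 1877 probes outside the annotation, which the report leaves out, 889 passed the threshold over 12 columns (455 higher, 434 lower at 200 µE) and 456 over couple means.

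The count of 768 features over 12 columns exceeded that of every other split drawn: of 100 splits of the 12 columns into 6 and 6, only the real one (1) reached it and the highest other gave 52. Among the 10 drawn splits that parted all same-numbered pairs, the highest other gave 19. This excludes a chance assignment only if the 12 columns are independent, and the couples argue against that: besides the real split, 1 of those drawn kept all 6 couples whole, with 19 features. With couple means, the 10 possible splits are too few for a share under 0.05; the real one gave 329 and no other any (1 of 10 as large).

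Neighbouring columns of a group deviated together. In all 6 couples the correlation of deviations within the couple lay above every such correlation between couples of that group. Repeat measurements of one array or one RNA would give this. Separate plants grown or hybridised on a shared day would give the same pattern, and nothing in the labels separates these readings.

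The 200 µE columns had lower medians and a wider spread than the 20 µE columns. One scale factor per column is excluded as the whole cause, since the ratio of 20 to 200 µE quantiles was 4.88 to 6.66 times higher at the 25th than at the 95th percentile. A constant background, subtracted with or without such a factor, is excluded as the whole cause likewise: the slope of the 20 on the 200 µE quantiles was 2.78 to 3.54 times higher between the 25th and 50th than between the 75th and 95th percentile, where a background and a factor give one slope. That the difference changed sign between the 50th and 95th percentile in 3 of 3 couples excludes nothing by itself, since columns scaled to like means would show it. The light treatment itself, under which transcripts of moderate level may fall while the brightest rise, cannot be told apart from a difference in hybridisation or detection between the groups, because all 3 couples at 200 µE lay below all at 20 µE and treatment and group are the same split.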

How the results depend on the processing

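Of 768 features (361 higher, 407 lower; 333 genes with their own probe), averaging couples gave 329 (159, 170; 135), 326 of them among the 768, and averaging with the couple as a block 243 (106, 137; 110). Without the 116 features at 0 in all columns these became 380 (181, 199; 165) and, with the block, 485 (225, 260; 207). Values as deposited gave 1168 (113, 1055; 514), all probes 1654 (814 and 840) and probes with 1 gene only 332 (152, 180). The last 2 test other features, which changes the count by construction. The averaging leaves fewer samples and no longer treats neighbouring columns as independent, and the part of each in the lower count was not tested. Of the 1168, 116 were features at 0 in all columns. Beyond these, and for the rise to 380 and 485, the cause was not tested. The replicate block gave 839 and changed no call of a named gene except that of CHLP (AT1G74470). CHLP did not pass with the couple as a block over couple means (adjusted p 0.184). Of the list members the replicate block ended the call of RPL17 (AT3G54210, adjusted p 0.0252 without and 0.0586 with it). The other settings, chosen before the data were examined, stayed within 1.5 times the main counts, and leaving out single columns gave 710 to 801 features (332 to 375 higher, 375 to 430 lower; 315 to 341 genes); leaving out a couple gave 557 to 861 (269 to 388 higher, 286 to 473 lower; 248 to 369 genes). The plastid ribosomal list's median of 0.42 became -0.83 with values as deposited (0.26 to 0.49 without single columns, 0.22 to 0.59 without couples) and its camera p stayed above the threshold throughout. Among the 31 named genes, values as deposited reversed PSBW (0.24), AT1G74470 (0.11) and AT3G13120 (-0.74), and median centring reversed LHCB1.5 (LHB1B2, 0.97), PSAN (1.12), PSBW (1.60) and AT1G74470 (1.47), the cause not being tested; no other alternative reversed any. With couples averaged, 12 of the 31 lost their call and 17 did with the couple as a block, against 7 in either case without the features at 0 in all columns. Averaging, leaving out couples and leaving out or adding features were chosen after seeing the data. Of 361 higher features, 162 were lower in deposited units, where the median log2 change over all features was -1.46. The cause for single features was not tested.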

Other observations

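All groups in this part were formed after the data had been examined, from the names and background knowledge of genes with their own probe, and some members had been seen before. Over all features 49.2% passed over 12 columns and 21.1% over couple means, and a count near these shares is not a result about a group. CRR21 and OTP85 were counted in both the PPR and the dehydrogenase groups below. Of 20 pentatricopeptide repeat (PPR) proteins, which bind and process organelle RNA, 3 were higher and 8 lower over 12 columns, and 3 were listed at 0 in all 12 columns. Of the 17 others, in fits without such features, 5 were higher and 3 lower under median centring and 1 higher and 11 lower without normalisation. Over couple means 3 rose and 1 fell. AT3G13150 (-2.67) passed only without those features (adjusted p = 0.023 against 0.057). AT3G51320 rose by 2.08 ± 0.20 on the log2 scale (SE; adjusted p = 0.0071 over couple means), and CRR21, needed for editing of a plastid ndhD transcript, 2.46-fold after quantile normalisation (0.039), with nearly equal deposited means of 0.414 ± 0.098 and 0.428 ± 0.058 units (SD, n = 3 couples). AT3G22150 rose by 2.09 ± 0.18 after quantile normalisation, with a log2 change of -0.08 without normalisation. AT5G39980 fell from 0.542 ± 0.164 units to a listed 0 in all 6 columns (0.0037). Of 7 mTERF proteins, 1 was higher and 5 lower over 12 columns, against 2 and 3 under median centring and 1 and 6 without normalisation, and over couple means AT1G79220 and AT3G46950 (-1.46 ± 0.33, adjusted p = 0.043, and -2.38 without normalisation) fell. AT3G18870 and AT1G62010 passed only without features at 0 in all columns (0.018 and 0.029).

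Of 6 redox proteins, 2 were higher and 3 lower over 12 columns, against 1 and 4 without normalisation. Over couple means the sulfiredoxin SRX fell from 0.448 ± 0.178 to 0.0081 ± 0.013 units, with 3 of 6 columns listed at 0 (log2 change -3.67 ± 0.77, adjusted p = 0.038). AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, rose from 0.160 ± 0.035 to 0.224 ± 0.013 units (2.63 ± 0.56, 0.039). The size of both depended on the scaling, at -5.66 and 0.52 without normalisation and -4.31 and 1.88 under median centring, and that of SRX rests in part on the floor. GLDH (-1.18) passed over couple means only without features at 0 in all columns (0.045 against 0.052). Of 9 photosynthetic subunits and assembly factors, called photosystem genes below, 1 was higher and 4 lower over 12 columns, against 5 and 2 under median centring. The group holds CCB3, an assembly factor for a haem of cytochrome b6 and not of a photosystem, and was not tested without it. CCB3 fell over couple means (0.612 ± 0.059 to 0.061 ± 0.0089 units, log2 change -1.76 ± 0.13, limma adjusted p = 0.0045). Of 6 genes of the plastid NADH dehydrogenase-like complex and its factors, 3 were listed at 0 in all 12 columns. Of the 3 others, 1 was higher and 1 lower over 12 columns without the all-zero features, against 2 and 0 under median centring and 0 and 1 without normalisation. Of 5 tetrapyrrole enzymes none passed over 12 columns or couple means (limma, 0 at an unadjusted p under 0.05 in either). With the replicate number as a block 2 passed. Under median centring 2 were higher and 1 lower (2 and 0 without features at 0 in all columns), and without normalisation 3 were lower. AT5G63290 was among the lower in both cases (log2 change -0.71 and -2.07). Its quantile-normalised mean at 20 µE lay at the level of listed zeros (-6.245) and at 200 µE above it (-5.908). Its lower calls therefore came from the floor.

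The hypothesis that the members of a group shift together against the other genes was tested with limma's camera over the 6 groups, and no group passed. The adjusted p was 0.73 for the PPR proteins, 0.529 for the mTERF proteins, 0.962 for the dehydrogenase complex, 0.534 for the photosystem genes, 0.962 for the redox proteins and 0.962 for the tetrapyrrole enzymes. With an estimated correlation the lowest adjusted p was 0.573. Without features at 0 in all columns the PPR proteins gave 0.607 and the other 4 groups still tested 0.47 to 0.909. The dehydrogenase group then kept only 3 members and was not tested, so that its value above says little. Limma's fry describes movement of the members without comparing them with the other genes. Over couple means its unadjusted p was 0.00094 for the photosystem genes (median log2 change -0.42) and 0.0091 for the mTERF proteins (-1.24). For the other groups it was 0.206 to 0.856. Under median centring over 12 columns it was 1.1e-05 for the photosystem genes, whose median was then 0.97, and 0.454 for the mTERF proteins. For the PPR and dehydrogenase groups the camera test was set before its result was seen, and for the others after values of members had been seen. A p above the threshold had been written down beforehand as counting against a joint shift. That bound was wrong, since such a p over as few as 5 genes does not show that the members did not move together. A criterion chosen after these results were seen asked for members past the threshold over couple means in both directions, each keeping its direction under all 3 scalings. The PPR proteins met it through AT3G51320 and AT5G39980 and the redox proteins through AT2G04700 and SRX. The mTERF proteins met it through AT3G18870 (3.13 ± 0.77) and AT1G79220 (-4.86 ± 0.90), but only without the features at 0 in all columns (limma, adjusted p = 0.018 and 0.0072). The photosystem genes (PSBY against CCB3 and ATAB2) and the dehydrogenase group (CRR21 against PIFI) did not meet it. They had opposed members over 12 columns alone, a fit that treats neighbouring columns as independent. No tetrapyrrole enzyme passed over 12 columns or couple means. Because the criterion was chosen after the calls were seen, meeting it excludes nothing. Members called both ways show at most that not all moved one way. Over all features 21.1% passed over couple means, 159 higher and 170 lower, so opposed members are not particular to a group. Whether a group shifted together against the other genes was therefore left undecided for all 6.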
